A study of Arabidopsis thaliana with 8 samples.

How the data were processed

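Leaf RNA of Arabidopsis thaliana was sequenced from wild type and from dcl1, a mutant of DICER-LIKE 1, the enzyme that cuts microRNAs from their precursors. Per the labels, total RNA was taken with Tri-reagent, messenger RNA was picked with magnetic beads, and libraries were made with 1 of 2 kinds of adapter. High definition (HD) adapters carry random bases at the end that is ligated, and standard Illumina adapters do not. Each of the 4 groups (genotype by adapter) had 2 libraries, 8 in all. Per the labels, the same RNA samples were made into both kinds of library, so the 8 libraries come from 4 RNA samples. Nothing in the labels says that the replicates of a genotype were separate plants, so the p-values below measure only the spread between these samples, which may be technical. The labels give no sequencing date or batch.

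The deposited files hold read counts per locus of the TAIR10 genome build, which the labels name. The counts are whole numbers from 1 up, without a header, and a locus that a file did not list was taken as 0. The aligner, the counting tool, the treatment of reads with several matches and the strand are not given in the sources used here. A pair of 5.8S ribosomal RNA loci had identical counts in all 8 libraries, as had several transfer RNA loci, so reads were evidently counted at every copy they matched, and values of repeated loci are sums over copies. Of the 22546 loci listed in at least 1 file, 22444 were matched to the TAIR10.1 annotation by identifier, and 102 were not. Chloroplast- and mitochondria-encoded loci numbered 0 in the files, so leaving them out was not run. Lists of these loci, planned beside the lists named below, have no members. Positions below are from that annotation. Library totals ran from 15772958 to 45929383 counts. No molecular identifiers were given, so counting intervals would cover counting error alone and none are printed.

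Counts were analysed with edgeR 4.0.16 in R 4.3.3. Loci with low counts were removed with filterByExpr, libraries were scaled by TMM, and contrasts were tested with the quasi-likelihood F test (two-sided). P-values were adjusted by Benjamini and Hochberg over all loci tested in a contrast, and a locus was called at an adjusted p under 0.05. A model with 1 mean for each of the 4 groups, fitted to all 8 libraries, gave the genotype contrast within each adapter, the adapter contrast within each genotype, and the difference between the genotype contrasts (the interaction). The adapter contrast over both genotypes came from a model with genotype and adapter as terms. Because the HD and the standard library of an RNA sample are not independent, the genotype contrast over both adapters was fitted to the 4 sums of these pairs. Levels are given as normalised read counts on the CPM scale, computed here from the deposited counts and the TMM factors, as mean ± SD over the libraries of a group. Folds are on the log2 scale, dcl1 over wild type or HD over standard. Their standard error (SE) was computed here as the absolute fold over the square root of edgeR's F. It is approximate, above all at loci with counts near 0.

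The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named the 5 loci with the largest positive and the 5 with the largest negative log2 fold change among those called, with a mean of at least 10 CPM and no overlap between the libraries of the groups. It added DCL1 and the up to 4 tested members with the smallest p of each list. Loci named outside this rule are marked as chosen after their values were seen. The 18 lists held 389 members: microRNA targets, precursors and targets of trans-acting small interfering RNAs (ta-siRNAs), small RNA machinery, primary microRNA transcripts, photosynthetic light reactions, carbon fixation, flavonoid and anthocyanin synthesis, salicylate and immune response, jasmonate response, cold and abscisic acid response, circadian clock, flowering and floral organ identity, shoot meristem and cell division, root markers, seed storage and oil body, glucosinolate synthesis and breakdown, senescence, and reference genes for qPCR. Lists with at least 3 tested members were tested with limma 3.58.1 camera, through edgeR, on normal scores computed from the counts. This was done with a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists of a contrast. The direction given by camera is that of these scores, which need not be that of the fold changes. With an estimated correlation camera also uses the few residual degrees of freedom, which by itself raises p. Calls of members were counted after adjustment over all loci and after adjustment over the list alone.

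Agreement of the genotype contrasts between adapters was described by correlations across genes, which are not independent replicates, and by shared calls. The spread between replicates was the common biological coefficient of variation (BCV) of edgeR for each adapter, after thinning every library to 15772958 counts. Transcript length, GC content, runs of GA/CT or GAA/CTT repeats and the share of each locus's 50-base words found at another locus were taken from the reference sequence. The repeat runs were examined only after the loci that differed between adapters had been seen.

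The pipeline was tested on simulated data drawn from the libraries. In these 200 loci were changed, picked at random among loci with a mean of at least 10 CPM. For the contrast within HD libraries it recovered 38 of 67 loci changed 2-fold (56.7%) and all of those changed 4-fold or 8-fold, with 15 of 186 calls false (8.06%). For the summed contrast it recovered 55 of 67 (82.1%) at 2-fold, with 13 of 201 calls false (6.47%). The simulated libraries were drawn independently, whereas real pairs share an RNA sample, so recovery on the sums may be overstated. For the adapter contrast it recovered 59 of 67 (88.1%) at 2-fold, with 14 of 206 calls false (6.80%). Among such loci, changes of 2-fold or less could therefore be missed, above all within a single adapter. Recovery below 10 CPM was not measured, so larger changes could be missed there.

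The pairing of HD and standard libraries by replicate number was checked on the differences between replicates. Among the 149 loci above 512 CPM, the difference between replicates 1 and 2 in HD libraries correlated across loci with that in standard libraries of the same genotype (Pearson r = 0.769 in wild type and 0.661 in dcl1), against 0.174 and 0.286 between genotypes. Over all 19521 tested loci the same correlations were 0.0820 and 0.00492. For adapter contrasts, a block for the RNA sample was fitted as an alternative. For genotype contrasts the replicates share no more than a number, and a block by that number was run as an alternative too.

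The alternatives were DESeq2 size factors, no filter, a filter at a mean of 10 CPM, the DESeq2 1.42.0 Wald test, each library left out in turn, a replicate block, a minimum absolute log2 fold change of 1, fits to the 4 libraries of a contrast alone, limma-voom with the RNA sample as a random block, and thinned counts. Leaving out ribosomal RNA loci, loci with a repeat run of at least 40 bases, or loci sharing at least 50% of their words with another locus was added after seeing the data. A loess trend on GC content and transcript length, removed from each library as an offset before the adapter contrast was fitted again, was added after seeing the data too. Where leaving out a library left a group with 1 library, that library was assumed to vary like the other groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.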

Results

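The data are read counts per locus from 8 leaf libraries of Arabidopsis thaliana, 2 in each of 4 groups: wild type with HD adapters, wild type with standard adapters, dcl1 with HD adapters and dcl1 with standard adapters. Wild-type HD libraries held 21537881 and 40516219 counts, and wild-type standard libraries held 21733499 and 40382700. The dcl1 HD libraries held 45929383 and 15772958 counts, and the dcl1 standard libraries held 20069662 and 32067359. Ribosomal RNA loci took 27.1% ± 0.412 of the counts in wild-type HD libraries (SD, n = 2), 18.8% ± 1.58 in wild-type standard libraries, 24.4% ± 4.65 in dcl1 HD libraries and 25.4% ± 5.35 in dcl1 standard libraries. Reads of these loci were evidently counted at every copy, so these shares and the totals count some reads repeatedly. The 10 most abundant loci took between 29.9% and 38.5% of a library. After thinning to 1 total, loci with at least 10 counts numbered 17528.5 ± 466 in wild-type HD, 17795.5 ± 53.0 in wild-type standard, 17419 ± 499 in dcl1 HD and 17324.5 ± 231 in dcl1 standard libraries (n = 2 each). No test was made between these values.

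The first question was how messenger RNA levels in dcl1 leaves differ from wild type, with HD adapters. AGO1, the main microRNA effector and itself a microRNA target, was 3.55-fold higher in dcl1, at 249 ± 4.13 CPM against 70.1 ± 7.26 (SD, n = 2 each). NF-YA2, a transcription factor targeted by miR169, was 12.8-fold higher, at 34.3 ± 7.70 against 2.78 ± 1.67 CPM. Of the genes of salicylate defence, PR1 fell by 2.59 on the log2 scale, and of those of leaf senescence, SEN1 fell by 3.70. DCL1 messenger RNA itself (chromosome 1, 23121 to 31227) did not pass the test, at 23.9 ± 2.43 CPM in dcl1 against 20.8 ± 0.606 in wild type (log2 fold change 0.20, SE 0.23, adjusted p = 0.743 by edgeR), so its level does not check the genotype labels. In all, 846 of 19521 tested loci were called, 404 higher and 442 lower in dcl1.

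Among the 81 tested microRNA targets, 10 rose and 3 fell with HD adapters, while 68 did not pass. Adjusted over the list alone, 14 rose and 4 fell. Without dcl1 HD replicate 2, 9 rose and 1 fell. AGO1 (chromosome 1, 17885633 to 17892632) rose by 1.83 on the log2 scale (SE 0.16, adjusted p = 1.83e-07), NF-YA2 by 3.68 (SE 0.36), SPL3 by 1.96 (SE 0.25) and SPL2 by 1.35 (SE 0.19). SPL2 and SPL3 are targets of miR156, which delays adult development. The SPL3 locus shares 92.2% of its 50-base words with an antisense locus, and the strand of counting is not given. The list ranked higher than other genes by camera (adjusted p = 0.00124), but not with an estimated correlation (adjusted p = 0.197 with an estimated correlation). Of 25 tested genes of the small RNA machinery, AGO1 and AGO2 rose (2 also adjusted over the list alone). AGO2, a target of miR403, rose by 1.49 (SE 0.24), and DCL4 (0.61, SE 0.27) and SGS3 (0.56, SE 0.36) did not pass. That list ranked higher by camera (adjusted p = 0.0393), but not with an estimated correlation (adjusted p = 0.205 with an estimated correlation). Its call ended without any 1 of 6 libraries: wild-type HD replicate 2 (adjusted p = 0.221), wild-type standard replicate 1 (0.0932) or 2 (0.0711), dcl1 HD replicate 1 (0.0814) or 2 (0.0678), or dcl1 standard replicate 1 (0.0776). Of the 9 tested ta-siRNA precursors and targets, 0 were called by edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05, and 0 by DESeq2). ARF3 was at 26.3 ± 1.82 against 16.6 ± 4.65 CPM (log2 fold change 0.67, adjusted p = 0.232). The list's camera adjusted p was 0.334. The 1 tested primary microRNA transcript, MIR162A, was at 1.80 ± 1.35 against 5.71 ± 0.632 CPM and did not pass over all loci (log2 fold change -1.62, adjusted p = 0.213), though it fell with the list adjusted alone, which with 1 member is the unadjusted p of 0.0234.

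Some defence and senescence genes were lower in dcl1 with HD adapters. Of 17 tested salicylate and immune response genes 9 fell (10 fell adjusted over the list alone; 4 without wild-type HD replicate 1 and 5 without dcl1 HD replicate 2). PR1, a classical marker of the salicylate response, went from 74.8 ± 42.2 CPM in wild type to 12.2 ± 3.62 in dcl1 (log2 fold change -2.59, SE 0.38, adjusted p = 0.000152). PR2, a glucanase (-2.05, SE 0.27), PR5 (-1.86, SE 0.29) and SARD1, a regulator of salicylate synthesis (-2.3, SE 0.40), fell too. Of 13 senescence genes 5 fell (6 fell adjusted over the list alone; 3 without wild-type HD replicate 2). SEN1 went from 150 ± 44.7 CPM to 11.6 ± 0.465 (log2 fold change -3.70, SE 0.27, adjusted p = 2.75e-08). DIN6, an asparagine synthetase induced in the dark, fell by 1.17 (SE 0.21), and SEN4 fell by 1.27 (SE 0.23). DIN10 fell by 0.82 (SE 0.18), and its call ended without wild-type HD replicate 2 (-0.72) or dcl1 HD replicate 1 (-0.55). By camera the salicylate list ranked lower (adjusted p = 3.14e-12), as did the senescence list (adjusted p = 1.28e-07). With an estimated correlation each had an adjusted p = 0.197.

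Few genes of photosynthesis were called with HD adapters. Of 37 genes of the light reactions 3 fell (8 fell adjusted over the list alone), and 34 of the 37 fold changes were negative. With a replicate block 7 fell, without a filter 6, and without ribosomal RNA loci or loci with shared words 5. The 3 of the main fit were LHCB1.4, LHCB2.3 and LHCB1.5. LHCB1.4, a light-harvesting protein, was at 10456 ± 753 CPM in dcl1 against 14627 ± 1806 in wild type (log2 fold change -0.48, SE 0.10), and its call ended without wild-type HD replicate 1 (-0.33) or dcl1 HD replicate 1 (-0.40). LHCB2.3 fell by 0.67 (SE 0.17), and its call ended without wild-type HD replicate 1 (-0.37), dcl1 HD replicate 1 (-0.60) or dcl1 HD replicate 2 (-0.73). LHCB1.5, the third (-0.40, SE 0.10), lost its call without wild-type HD replicate 1 (-0.24) or dcl1 HD replicate 1 (-0.31) and in the fit to the 4 HD libraries alone (-0.40). The number that fell was 7 without wild-type HD replicate 2 and 6 without wild-type standard replicate 1 or 2. The list ranked lower by camera (adjusted p = 0.00124), but not with an estimated correlation (adjusted p = 0.537 with an estimated correlation), nor without wild-type HD replicate 1 (adjusted p = 0.267) or dcl1 HD replicate 1 (0.0814). Of 16 carbon fixation genes 0 passed over all loci by edgeR (8 at an unadjusted p under 0.05, and 2 by DESeq2), while 4 rose adjusted over the list alone, and all 16 fold changes were positive. FBA1, an aldolase, had a log2 fold change of 0.54 (SE 0.17, adjusted p = 0.0763) and RBCS1B, a Rubisco small subunit, one of 0.38 (SE 0.12, adjusted p = 0.0736). In that list 1 gene rose over all loci without wild-type HD replicate 1 or dcl1 standard replicate 1, and 2 without wild-type standard replicate 1 or 2. That list ranked higher by camera (adjusted p = 0.00251), but not with an estimated correlation (adjusted p = 0.501 with an estimated correlation), nor without wild-type HD replicate 2 (adjusted p = 0.221).

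The other lists did not pass camera with HD adapters. In the jasmonate response list, 2 of 20 genes rose and 2 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.255). LOX2, a lipoxygenase of jasmonate synthesis, rose by 0.93 (SE 0.13), to 1192 ± 96.2 CPM from 625 ± 17.5, and TAT3, a tyrosine aminotransferase, fell by 3.79 (SE 0.57). VSP1 (1.27, SE 0.29) lost its call without wild-type HD replicate 1 (1.12) or dcl1 HD replicate 1 (0.94), and AOS, of jasmonate synthesis (-0.58, SE 0.15), without any 1 of the 4 HD libraries (-0.48 and -0.66 without wild-type replicates 1 and 2, -0.54 and -0.60 without dcl1 replicates 1 and 2). The counts were 1 and 1 without wild-type HD replicate 1, 3 and 1 without wild-type HD replicate 2, and 2 and 1 without dcl1 HD replicate 2. Without wild-type HD replicate 1 this list passed (adjusted p = 0.0206), as did the clock (0.0206) and flowering (0.0429) lists, and without dcl1 HD replicate 2 the flavonoid list passed (0.0410). In the cold and abscisic acid list, 3 of 19 genes rose and 1 fell (3 and 4 adjusted over the list alone), among them COR15B, up by 1.41 (SE 0.17), and RD22, up by 0.85 (SE 0.14). RAB18 (1.05, SE 0.30) and COR47, the one that fell (-0.57, SE 0.16), lost their calls without any 1 of the 4 HD libraries (1.1 and -0.55, 1.02 and -0.57 without wild-type replicates 1 and 2, 0.895 and -0.60, 1.2 and -0.52 without dcl1 replicates 1 and 2), and RAB18 also in the fit to the 4 HD libraries alone (1.05). Without wild-type HD replicate 1 or 2 the number that rose was 2, and the number that fell was 4 without wild-type standard replicate 1, 3 without dcl1 standard replicate 1 and 2 without dcl1 standard replicate 2. Camera put that list up (adjusted p = 0.821) while its median of -0.18 and mean of -0.20 were negative. ELF4 was the 1 clock gene of 19 that rose (1.07, SE 0.23; 3 adjusted over the list alone; camera adjusted p = 0.0827), and its call ended without wild-type HD replicate 1 (0.85) or dcl1 HD replicate 1 (0.66). The number of clock genes that rose was 2 without wild-type HD replicate 2, wild-type standard replicate 2 or dcl1 standard replicate 1, and 3 without wild-type standard replicate 1. FUL and FLC were the 2 of 8 flowering genes that rose (2 adjusted over the list alone; camera adjusted p = 0.0827). FUL rose by 1.93 (SE 0.52), and its call ended without wild-type HD replicate 1 (1.67) or 2 (2.3) or dcl1 HD replicate 2 (1.64). FLC, a repressor of flowering, rose by 3.48 (SE 0.99) from 0.262 ± 0.371 CPM, and its call ended without wild-type HD replicate 1 (2.67), dcl1 HD replicate 1 (2.93) or dcl1 standard replicate 2 (3.50), and in the fit to the 4 HD libraries alone (3.52). Of 21 glucosinolate genes 2 fell (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.234), CYP79B2 (-1.75, SE 0.36) and CYP83B1 (-0.83, SE 0.16), and the call of CYP83B1 ended without wild-type HD replicate 1 (-0.61). None of 8 flavonoid genes (camera adjusted p = 0.279) and none of 12 meristem and division genes (adjusted p = 0.318) passed by edgeR, over all loci or adjusted over the list alone (0 and 1 at an unadjusted p under 0.05, and 0 in either list by DESeq2). Of 8 reference genes for qPCR, UBQ10, a polyubiquitin, fell by 1.02 (SE 0.13), to 1268 ± 91.4 from 2566 ± 19.9 CPM (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.126). The 2 tested root markers, PYK10 (log2 fold change -4.43, SE 2.19, adjusted p = 0.331) and NRT2.1 (0.80, SE 0.87, adjusted p = 0.730), did not pass, and the seed storage genes had too few counts to be tested.

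The strongest calls with HD adapters lay outside the lists for the most part. AT4G19430, which codes for an uncharacterised protein, rose by 5.91 (SE 0.41), from 0.524 ± 0.388 to 35.2 ± 9.09 CPM. SDI1, a gene induced by sulfur deficiency, rose by 4.07 (SE 0.52), the terpene synthase gene TPS03 by 4.02 (SE 0.58), the basic helix-loop-helix gene AT5G50915 by 3.84 (SE 0.26) and the lipid transfer protein gene LTP3 by 3.73 (SE 0.42). BG3, a glucanase gene (-4.0, SE 0.42), AT4G36850, a transmembrane protein gene (-3.86, SE 0.45), TAT3 (-3.79, SE 0.57), SEN1 (-3.70, SE 0.27) and AT5G12050 (-3.34, SE 0.32) fell the most among loci of at least 10 CPM. At an absolute log2 fold change of at least 1 the count was 541 loci, and without dcl1 HD replicate 2, the smallest library, it was 461.

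The same question was put to the libraries with standard adapters. AGO1 rose by 1.67 on the log2 scale (SE 0.16, adjusted p = 4.52e-07), to 235 ± 5.21 CPM from 73.5 ± 0.0774 (SD, n = 2 each), and NF-YA2 rose by 3.54 (SE 0.36, adjusted p = 1.27e-06). SEN1 fell by 3.88 (SE 0.27), from 179 ± 49.5 to 12.1 ± 5.23 CPM, and PR1 fell by 2.59 (SE 0.38), from 101 ± 62.9 to 16.8 ± 5.52 CPM. DCL1 was at 22.7 ± 1.99 CPM in dcl1 against 20.8 ± 0.794 and did not pass (log2 fold change 0.13, SE 0.23, adjusted p = 0.876 by edgeR). Of 19521 loci 826 were called, 366 higher and 460 lower in dcl1.

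With standard adapters 9 of 81 microRNA targets rose and 1 fell (12 and 5 adjusted over the list alone; 2 fell without wild-type HD replicate 1 or without dcl1 standard replicate 1 or 2). AGO2 rose by 1.98 (SE 0.25), and FAMT, a methyltransferase gene targeted by miR163, was the one that fell (-2.09, SE 0.32, adjusted p = 0.000329). The list ranked higher by camera (adjusted p = 0.00529), but not with an estimated correlation (adjusted p = 0.198 with an estimated correlation), nor without dcl1 standard replicate 1 (adjusted p = 0.0552). Of 25 small RNA genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera up, adjusted p = 0.000518; adjusted p = 0.0991 with an estimated correlation). AGO3 rose by 2.77 (SE 0.75), and its call ended without wild-type standard replicate 1 (2.21) or dcl1 standard replicate 2 (2.53). HESO1, which adds uridines to unmethylated small RNAs, fell by 1.26 (SE 0.34), and its call ended without any 1 of the 4 standard libraries (-1.14 and -1.37 without wild-type replicates 1 and 2, -1.06 and -1.5 without dcl1 replicates 1 and 2). ARF3, at 21.3 ± 3.8 against 13.7 ± 4.63 CPM, and the 8 other tested ta-siRNA genes did not pass by edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05, and 0 by DESeq2; camera adjusted p = 0.600). MIR162A did not pass (log2 fold change 0.33, SE 0.65, adjusted p = 0.886; unadjusted p = 0.615).

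Of 17 salicylate and immune response genes 7 fell with standard adapters (11 fell adjusted over the list alone; camera down, adjusted p = 4.19e-13; adjusted p = 0.180 with an estimated correlation). PR2 (-1.82, SE 0.27), PR5 (-1.79, SE 0.29) and SARD1 (-2.10, SE 0.39) were among them. Of 13 senescence genes 4 fell (6 fell adjusted over the list alone; camera down, adjusted p = 1.79e-10; adjusted p = 0.0991 with an estimated correlation). SEN4 fell by 1.48 (SE 0.23), and DIN6 fell by 1.24 (SE 0.21). DIN10 (-0.73, SE 0.17) lost its call without wild-type standard replicate 2 (-0.63) or dcl1 standard replicate 1 (-0.49). Of 37 light reaction genes 5 fell (13 fell adjusted over the list alone; camera down, adjusted p = 0.000496; adjusted p = 0.649 with an estimated correlation). With a replicate block 10 fell, and without a filter or without loci with shared words 8. PSAF, a subunit of photosystem I, fell by 0.63 (SE 0.13), from 3978 ± 509 to 2578 ± 383 CPM, and its call ended without dcl1 standard replicate 2 (-0.48). LHCB2.3 fell by 0.79 (SE 0.18), and its call ended without wild-type standard replicate 1 (-0.47), as did that of the whole list (adjusted p = 0.0755). PSAD-2 (-0.55, SE 0.14) and LHCA1 (-0.45, SE 0.11) lost their calls without wild-type standard replicate 1 (-0.39 and -0.32), dcl1 standard replicate 1 (-0.63 and -0.41) or dcl1 standard replicate 2 (-0.48 each). The number that fell was 1 without wild-type standard replicate 1 or dcl1 standard replicate 2, 2 without dcl1 standard replicate 1 and 8 without wild-type standard replicate 2. Of 16 carbon fixation genes 0 passed over all loci by edgeR (5 at an unadjusted p under 0.05, and 3 by DESeq2) and 5 rose adjusted over the list alone (camera up, adjusted p = 0.0135; adjusted p = 0.649 with an estimated correlation). Without wild-type standard replicate 2 the list's adjusted p was 0.545. Over all loci 1 gene of it rose without wild-type HD replicate 1 or 2 or dcl1 HD replicate 2, and 2 rose without wild-type standard replicate 1. FBA1 had a log2 fold change of 0.54 (SE 0.17, adjusted p = 0.0741).

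Of 20 jasmonate genes 2 rose and 4 fell with standard adapters (2 and 6 adjusted over the list alone; camera adjusted p = 0.0936), with LOX2 up by 0.90 (SE 0.13) and TAT3 down (log2 fold change -4.94, SE 0.62). Without wild-type standard replicate 1 or dcl1 standard replicate 1 this list passed camera (adjusted p = 0.00456 and 0.00596), as it did without loci with shared words (0.0434). AOS (-0.63, SE 0.15) lost its call without wild-type standard replicate 1 (-0.60) or 2 (-0.66) or dcl1 standard replicate 1 (-0.55), and JAZ2 (-0.91, SE 0.22) without wild-type standard replicate 2 (-0.70) or dcl1 standard replicate 2 (-0.81). The counts were 1 and 1 without wild-type standard replicate 2, 1 and 2 without dcl1 standard replicate 1, and 2 and 2 without dcl1 standard replicate 2. Of 19 cold and abscisic acid genes 2 rose and 2 fell (3 and 3 adjusted over the list alone), with COR15B up by 1.53 (SE 0.17) and RD22 by 0.90 (SE 0.15). The 2 that fell, RD26 (-1.253, SE 0.31) and HAI1 (-8.92, SE 2.3), lost their calls without wild-type standard replicate 2 (-0.90 and -7.67) or dcl1 standard replicate 1 (-1.08 and -9.0), and HAI1 also without dcl1 standard replicate 2 (-8.90). Camera put that list up (adjusted p = 0.683), with a median of 0.03 and a mean of -0.46. ELF4 rose by 1.41 (SE 0.23) and was the 1 clock gene of 19 called (1 adjusted over the list alone; 2 without wild-type standard replicate 1). Camera put the clock list up (adjusted p = 0.192) while its median was -0.01 and its mean -0.12, and at a mean of at least 10 CPM it passed (adjusted p = 0.0469). FLC rose by 4.63 (SE 1.03), from 0.267 ± 0.251 to 7.15 ± 0.171 CPM, the 1 of 8 flowering genes called (2 adjusted over the list alone). Camera put the flowering list up (adjusted p = 0.192), with a mean of -0.39 and a median of 0.06. Of 21 glucosinolate genes TGG1, a myrosinase, fell (-0.45, SE 0.12; 5 adjusted over the list alone), and its call ended without wild-type standard replicate 2 (-0.35), dcl1 standard replicate 1 (-0.50) or dcl1 standard replicate 2 (-0.40) and in the fit to the 4 standard libraries alone (-0.45). The number that fell was 3 without wild-type HD replicate 1 and 2 without wild-type HD replicate 2, wild-type standard replicate 1 or either dcl1 HD library. Camera put the list down (adjusted p = 0.330; median 0.10, mean -0.13). Without dcl1 standard replicate 1 that list passed (adjusted p = 0.0124). None of 8 flavonoid genes (camera adjusted p = 0.192) or 12 meristem genes passed by edgeR, over all loci or adjusted over the list alone (0 in either list at an unadjusted p under 0.05 and 0 by DESeq2), and camera put the meristem list down (adjusted p = 0.932; median 0.07, mean -0.04). UBQ10 fell by 0.86 (SE 0.13) among the 8 reference genes (1 rose and 1 fell adjusted over the list alone, and over all loci without wild-type HD replicate 1 or 2 or dcl1 HD replicate 2; camera adjusted p = 0.332). PYK10 (log2 fold change 1.85, SE 1.98, adjusted p = 0.749) and NRT2.1 (-0.18, SE 0.86, adjusted p = 0.961) did not pass.

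The largest rises with standard adapters among loci of at least 10 CPM were those of SDI1 (6.38, SE 0.60), AT4G19430 (4.35, SE 0.37), AT5G50915 (3.77, SE 0.26), CER4, a fatty acyl reductase gene of wax synthesis (3.62, SE 0.51), and BAM5, a beta-amylase gene (3.61, SE 0.40). The largest falls were those of TAT3, SEN1, BG3 (-3.65, SE 0.40), PCC1, a gene induced by pathogens (-3.51, SE 0.33), and AT1G62510 (-3.50, SE 0.35). The count of 826 fell to 418 without wild-type standard replicate 2 and to 465 without dcl1 standard replicate 1. It was 483 at an absolute log2 fold change of at least 1 and 1247 by DESeq2.

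**Figure D1:**
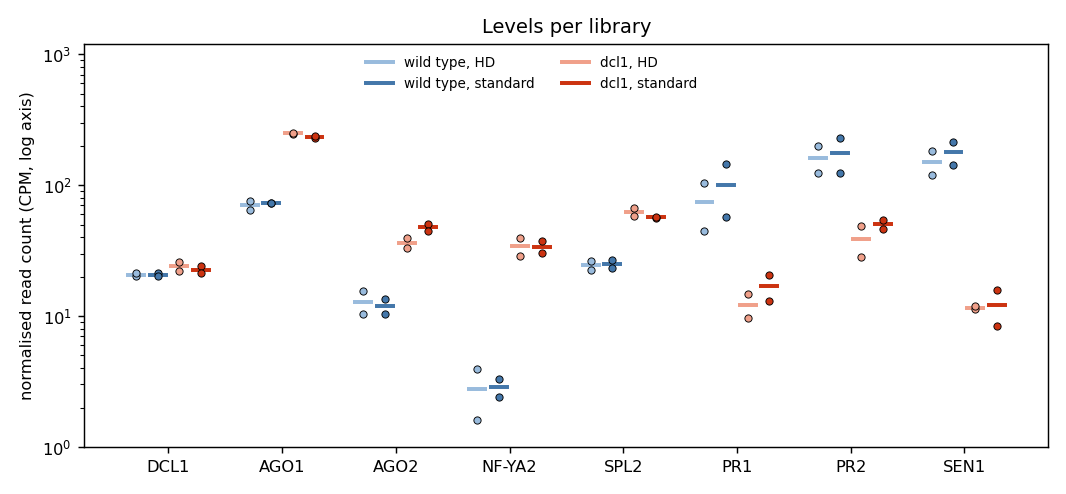
Normalised read counts (CPM, log axis) of 8 genes in each of the 8 libraries. Points are libraries and bars are means of 2 libraries. AGO1, AGO2, NF-YA2 and SPL2 are higher in dcl1 with both adapters, PR1, PR2 and SEN1 are lower, and DCL1 lies near 20.8 CPM in wild type and at 23.9 and 22.7 CPM in dcl1.

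Summing the HD and the standard counts of each RNA sample gave 1 genotype comparison over 4 samples. NF-YA2 rose by 3.55 on the log2 scale (SE 0.21, adjusted p = 2.65e-08), to 32.6 ± 1.55 CPM from 2.81 ± 0.444 (SD, n = 2 each), and AGO1 and AGO2 each rose by 1.76 (SE 0.14 and 0.17). PR1 (-2.63, SE 0.30), PR2 (-1.89, SE 0.21) and SEN1 (-3.73, SE 0.22) fell. DCL1, at 22.9 ± 0.0403 against 20.7 ± 0.0309 CPM, did not pass (log2 fold change 0.14, SE 0.17, adjusted p = 0.701 by edgeR). Of 19711 tested loci 1744 were called, 848 higher and 896 lower in dcl1, and 817 at an absolute log2 fold change of at least 1.

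On the sums 13 of 82 microRNA targets rose and 3 fell (15 and 5 adjusted over the list alone; camera up, adjusted p = 0.000916; adjusted p = 0.347 with an estimated correlation). The members that rose were AGO1, AGO2, NF-YA2, NF-YA3, NF-YA10, SPL2, SPL3, SPL4, SPL9, SPL10, SPL11, REV and AGL16, and those that fell were FAMT, NAC1 and ORE1. At a mean of at least 10 CPM 8 members rose and 2 fell, and with limma-voom on all 8 libraries 17 rose and 6 fell. Of 25 small RNA genes AGO1 and AGO2 rose (4 rose adjusted over the list alone, and over all loci without wild-type RNA sample 1; camera up, adjusted p = 0.00250; adjusted p = 0.510 with an estimated correlation). Of 9 ta-siRNA genes 0 passed by edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05, and 0 by DESeq2; camera adjusted p = 0.385), with ARF3 at a log2 fold change of 0.64 (SE 0.21, adjusted p = 0.0722). In that list 1 gene rose without wild-type RNA sample 1 or dcl1 RNA sample 2, and 1 fell without dcl1 RNA sample 1. MIR162A had a log2 fold change of -0.46 (SE 0.38, adjusted p = 0.541; unadjusted p = 0.245). Of 18 salicylate and immune response genes 11 fell (14 fell adjusted over the list alone; 8 fell and 1 rose without wild-type RNA sample 1; camera down, adjusted p = 1.83e-14; adjusted p = 0.510 with an estimated correlation). SARD1 fell by 2.06 (SE 0.26), and PR5 fell by 1.79 (SE 0.23). Of 13 senescence genes 6 fell (7 fell adjusted over the list alone; camera down, adjusted p = 1.37e-10; adjusted p = 0.347 with an estimated correlation). Among them were SEN4 (-1.37, SE 0.19), DIN6 (-1.2, SE 0.17) and ORE1, a senescence regulator targeted by miR164 (-2.87, SE 0.55).

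Of 37 light reaction genes LHCB2.3 (-0.74, SE 0.16) and PSAF (-0.49, SE 0.13) fell on the sums (7 fell adjusted over the list alone; camera down, adjusted p = 0.00250; adjusted p = 0.614 with an estimated correlation). With limma-voom, fitted to all 8 libraries and not to the sums, 23 of these genes fell and 1 rose, of 2609 loci called in all. By DESeq2 8 fell, without a filter 7 and with a replicate block 4. The limma-voom fit used 1 correlation within RNA samples for all loci. Replicate differences of paired libraries correlated by 0.0820 (wild type) and 0.00492 (dcl1) over all loci, but by 0.769 and 0.661 above 512 CPM. At abundant genes it may therefore take paired libraries as too independent and call too many. Without wild-type RNA sample 1 the calls of LHCB2.3 (-0.44) and PSAF (-0.38) ended, as did that of the list (adjusted p = 0.155), and the call of PSAF also ended without dcl1 RNA sample 2 (-0.42). Without wild-type RNA sample 2 the number that fell was 9. FBA1 was the 1 of 16 carbon fixation genes that rose (0.54, SE 0.16, adjusted p = 0.0461; 2 adjusted over the list alone; camera up, adjusted p = 0.0224; adjusted p = 0.614 with an estimated correlation). With limma-voom on all 8 libraries 10 of them rose, by DESeq2 3, and without a filter or at a mean of at least 10 CPM 2. The FBA1 call ended without wild-type RNA sample 2 (0.30) or dcl1 RNA sample 2 (0.41), with DESeq2 size factors (0.53), and without the ribosomal RNA loci (0.53) or the loci with shared words (0.53). The carbon fixation list's call ended without the same samples (adjusted p = 0.430 and 0.0748). Without wild-type RNA sample 1, 4 of its genes rose. Of 20 jasmonate genes 2 rose and 5 fell (4 and 8 adjusted over the list alone; camera down, adjusted p = 0.0582), with LOX2 up by 0.91 (SE 0.13), VSP1, a storage protein gene, up by 1.15 (SE 0.20) and TAT3 down (-4.0, SE 0.29). AOS (-0.58, SE 0.14) lost its call without dcl1 RNA sample 1 (-0.55). The counts were 2 and 8 without wild-type RNA sample 1, 3 and 2 without wild-type RNA sample 2 or dcl1 RNA sample 1, and 2 and 2 without dcl1 RNA sample 2. This list passed camera without wild-type RNA sample 1 (adjusted p = 0.000686) or dcl1 RNA sample 1 (0.0233), at a mean of at least 10 CPM (0.0490) and without loci with shared words (0.0308). Of 19 cold and abscisic acid genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), with COR15B up by 1.52 (SE 0.14), RD22 up by 0.90 (SE 0.14) and RD26 down (-1.14, SE 0.23). Camera put that list up (adjusted p = 0.824) while its median of -0.10 and mean of -0.31 were negative.

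Of 19 clock genes 3 rose on the sums (6 rose and 1 fell adjusted over the list alone), among them ELF4 (1.27, SE 0.17), and camera put the list up (adjusted p = 0.145; median -0.08, mean 0.02). The clock list passed at a mean of at least 10 CPM (adjusted p = 0.0422) and without wild-type RNA sample 1 (0.0340). LNK1 (1.03, SE 0.31) lost its call without wild-type RNA sample 2 (0.49) or dcl1 RNA sample 1 (0.77), and with DESeq2 size factors, at a mean of at least 10 CPM, without ribosomal RNA loci and without loci with shared words (1.02 in each). PRR3 (0.60, SE 0.16) lost it without wild-type RNA sample 1 (0.51) or dcl1 RNA sample 1 (0.62) or 2 (0.58). The number of clock genes that rose was 5 without wild-type RNA sample 2, and without dcl1 RNA sample 1, with other members called, 3 rose and 1 fell. FLC (4.19, SE 0.65) and FUL (1.75, SE 0.33) were the 2 of 8 flowering genes that rose (2 adjusted over the list alone; camera adjusted p = 0.0719, and 0.0302 without wild-type RNA sample 1), and 1 fell without dcl1 RNA sample 1. Of 21 glucosinolate genes 3 fell (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.171, and 0.0255 without dcl1 RNA sample 1), with CYP79B2, which starts indole glucosinolate synthesis, at -1.31 (SE 0.21) and CYP83B1 at -0.69 (SE 0.14). CYP79B3 (-0.77, SE 0.17) lost its call without dcl1 RNA sample 2 (-0.66), and without wild-type RNA sample 1, 2 rose and 5 fell. None of 9 flavonoid genes passed by edgeR, also adjusted over the list alone (0 at an unadjusted p under 0.05 and 0 by DESeq2; camera adjusted p = 0.276, but 0.0340 without wild-type RNA sample 1, where 1 gene rose, and 0.0247 without dcl1 RNA sample 2). None of 12 meristem genes passed by edgeR, also adjusted over the list alone (0 at an unadjusted p under 0.05 and 0 by DESeq2; camera adjusted p = 0.608). UBQ10 fell by 0.93 (SE 0.13), the 1 of 8 reference genes called (1 adjusted over the list alone; 1 rose and 1 fell without wild-type RNA sample 1; camera adjusted p = 0.238). PYK10 (-0.98, SE 1.2, adjusted p = 0.710), NRT2.1 (0.39, SE 0.52, adjusted p = 0.734) and the 1 tested seed storage gene, CRA1 (1.65, SE 1.83, adjusted p = 0.675), did not pass. In all 3 genotype comparisons 15 of the 18 lists could be tested, and 3 ranked higher and 3 lower by camera. With an estimated correlation 0 passed (3 with HD adapters, 3 with standard adapters and 2 on the sums at an unadjusted p under 0.05). That setting also has few degrees of freedom, so it does not show that correlation between genes ended these calls. With standard adapters the small RNA list had an estimated correlation of -0.0191, below the preset. Its unadjusted camera p still went from 0.000138 to 0.0132.

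The dcl1 effect was then compared between adapters. The microRNA targets AGO1, AGO2, NF-YA2, SPL2, SPL3, SPL9, SPL10, AGL16 and FAMT were called with both. In all, 480 loci were called with both adapters, 222 higher and 258 lower in dcl1 and 0 in opposite directions by edgeR (6 of the 1589 loci at an unadjusted p under 0.05 with both), where independent calls would share 7.57 and 10.4. Of the 1192 loci called with either adapter, 1161 (97.4%) had the same sign with both, and their fold changes correlated across loci with a Pearson r of 0.837. Over all 19521 loci r was 0.370 (Spearman rho 0.412), and over the 9015 loci with a mean of at least 10 CPM r was 0.752 (rho 0.640). Both contrasts used the same RNA samples, so chance differences between those samples are shared and add to these values. Both also came from 1 fit with a shared spread for each locus, so 7.57 and 10.4 are a reference that could not hold exactly. The 97.4% and the r of 0.837 cover loci picked by these same contrasts. All 480 shared calls were also called on the sums, which called 665 loci that neither adapter called alone.

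**Figure D2:**
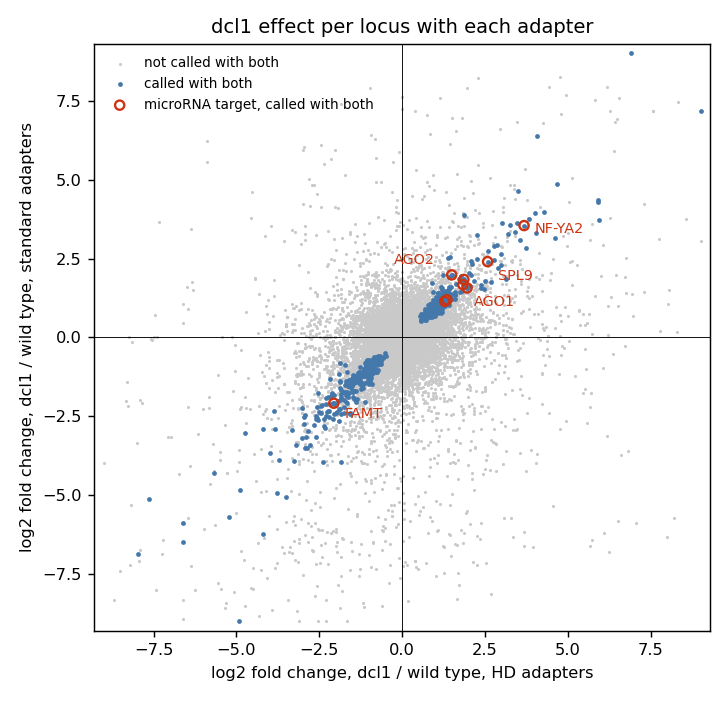
Log2 fold change of dcl1 over wild type per locus with HD adapters (x axis) and with standard adapters (y axis), limited to the plotted range. Grey points are loci not called with both adapters, blue points are the 480 called with both, and red circles mark microRNA targets among them, of which FAMT alone is lower in dcl1.

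Only 5 loci differed in their dcl1 effect between adapters by the interaction test, all named here after their values were seen. AT3G43990, which codes for a protein with a BAH domain, stood at 1415 ± 129 CPM in wild-type HD libraries (SD, n = 2) against 355 ± 0.116 in wild-type standard, 474 ± 140 in dcl1 HD and 468 ± 77.8 in dcl1 standard libraries (interaction -1.98, SE 0.24, adjusted p = 0.000683 by edgeR). AT1G15405, a non-coding locus, had an interaction of -2.80 (SE 0.39, adjusted p = 0.00289) and AT3G22142, a lipid transfer protein gene, one of 2.02 (SE 0.31, adjusted p = 0.00913). The 5.8S ribosomal RNA loci AT2G01020 and AT3G41979, whose counts are identical, had an interaction of -1.247 (SE 0.22, adjusted p = 0.0495). At an unadjusted p under 0.05 there were 618 loci, and DESeq2 called 5. With a block for the RNA sample 36 loci were called. The count was 3 without wild-type HD replicate 1, 13 without dcl1 HD replicate 2 and 10 without dcl1 standard replicate 1. It was 3 with DESeq2 size factors, at a mean of at least 10 CPM or without ribosomal RNA loci, 1 without loci with shared words and 16 without a filter.

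The last question was which loci HD adapters recover differently from standard adapters, over both genotypes. Of 88 loci with long GA/CT or GAA/CTT repeats 38 were higher with HD adapters, as were 9 of 13 small nuclear RNA loci, while most messenger RNAs, DCL1 among them (0.04, SE 0.16, adjusted p = 0.979), did not pass the test. AT1G28500, which carries a GA/CT run of 78 bases, was 5.72-fold higher with HD adapters, at 33.9 ± 10.07 CPM against 5.72 ± 2.35 (SD, n = 4 each; log2 fold change 2.52, SE 0.25, adjusted p = 3.20e-06 by edgeR). TOM5, a subunit of the mitochondrial import complex, was lower, at 10.06 ± 2.38 against 23.5 ± 5.32 CPM (-1.23, SE 0.21, adjusted p = 0.00493). Of 19521 loci 96 were called, 83 higher and 13 lower with HD adapters. Of the 83, 25 were protein-coding loci without a repeat run of at least 40 bases. They include AT2G07706 (2.07, adjusted p = 8.74e-08 by edgeR) and UBQ12 (7.11, adjusted p = 0.00394), named after their values were seen. A share of 0.783 of the 50-base words of AT2G07706 is also found in organelle DNA. With a block for the RNA sample 232 were called, 148 higher and 84 lower, DESeq2 called 179, and 190 were called without a filter. With a trend on GC content and transcript length removed from each library 60 were called, and 49 of the 83 higher loci kept their call. The median log2 fold change of the 83 was 1.41 before and after. Of the 34 others 33 stayed at an unadjusted p under 0.05, but only 9 had a p no higher than the highest called before.

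Of the 83 loci higher with HD adapters, 38 spanned a GA/CT (30 loci) or GAA/CTT (8 loci) run of at least 40 bases, against 88 of the 19521 tested loci. That is an odds ratio of 325 against the other tested loci (95% interval 188 to 558, Fisher's exact test, two-sided, p = 3.26e-70), and 0 of the 13 lower loci spanned one. The levels of the 30 GA/CT loci, all picked as higher with HD adapters, correlated across libraries with a median pairwise r of 0.963. The test takes loci as independent, so its interval is too narrow and its p-value too small. The median log2 fold change was 0.04 over 267 loci with a GA/CT run of 20 to 39 bases, 0.62 over 49 loci with 40 to 79 bases (20 called) and 2.04 over 10 loci with 80 to 172 bases (10 called). In 21 of the 38 loci the spliced sequence of the longest annotated transcript held no such run of at least 40 bases. Without loci with such runs 33 loci were called between adapters. These are 33 of the 58 called loci that have no such run, so calls were lost at loci without a run too. Leaving out called loci also lowers the p at which the adjustment calls the others, and 0 of the 58 changed sign. FAF1, a meristem gene with a GAA/CTT run of 75 bases, rose by 3.26 (SE 0.64, adjusted p = 0.0166), but not by DESeq2 (3.31). AT1G47300, an F-box gene with a run of 87 bases (3.31, SE 0.70, adjusted p = 0.0296), and AT5G03710 with a run of 186 bases (3.26, SE 0.74, adjusted p = 0.0479) lost their calls by DESeq2 (3.40 and 3.31), at a mean of at least 10 CPM (3.32 and 3.27), without wild-type standard replicate 1 (3.12 and 3.10) or without dcl1 HD replicate 1 (3.54 and 3.48).

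**Figure D3:**
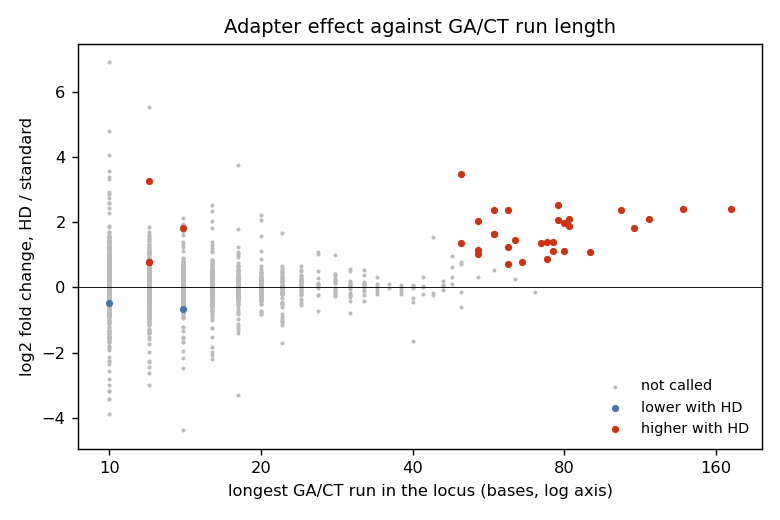
Log2 fold change of HD over standard adapters (y axis) against the longest GA/CT run in the locus (x axis, bases, log axis, runs of at least 10 bases). Each point is a locus, and red points are called higher with HD adapters. All 10 loci with a run of 80 bases or more are called higher.

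Small structural RNAs were looked at after their values were known, and no test of them as a group was made. Of 13 tested small nuclear RNA loci, spliceosome components, 9 rose, among them 6 copies of U2 at nearly the same value (1.18 to 1.22), so that they are 4 families, U1, U2, U4 and U6. Of 120 transfer RNA loci 7 rose, and of 35 small nucleolar RNA loci 2. With the trend on GC content and length removed, 6 of these small nuclear RNA loci (median log2 fold change 1.21 before and 0.916 after) and the 7 transfer RNA loci (4.095 and 3.17) lost the call. Of them 5 and 7 stayed at an unadjusted p under 0.05, which 1531 tested loci reached. Only 1 and 0 of them had a p no higher than the highest called before. The named ones were U1.5 (log2 fold change 1.27), U2.2 (1.18), U4.2 (0.85) and U6-1 (2.04). AT3G06895, higher by 2.76 (SE 0.33), overlaps U4.2 on the opposite strand. A set of 6 transfer RNA loci and 1 other locus shared identical counts, so the 83 loci hold 77 distinct sets of counts.

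Among the fixed lists 0 passed camera between adapters, also with an estimated correlation (1 and 0 at an unadjusted p under 0.05). Of 37 light reaction genes 2 rose and 4 fell with HD adapters (5 and 11 adjusted over the list alone; camera adjusted p = 0.389), among them LHCA1, an antenna protein of photosystem I, at -0.44 (SE 0.08, adjusted p = 0.00585). The calls of PSAK (-0.40), LHCB1.3 (-0.32) and PSBP-1 (0.37) ended without any 1 of 4, 6 and 6 of the 8 libraries, at folds about as large (-0.35 to -0.40, -0.28 to -0.34 and 0.32 to 0.37), and also without repeat loci (-0.40, -0.32 and 0.37), that of LHCB1.3 at a mean of at least 10 CPM (-0.32) and that of PSBP-1 with DESeq2 size factors (0.37). Neither rise kept its call without wild-type HD replicate 1, wild-type standard replicate 2 or any 1 of the 4 dcl1 libraries, and 1 did without wild-type HD replicate 2. The number that fell was 1 without wild-type HD replicate 2, wild-type standard replicate 1 or dcl1 HD replicate 2, 2 without any 1 of the other 3 dcl1 libraries, and 6 without wild-type standard replicate 2. With a block for the RNA sample 4 rose and 11 fell, and 6 carbon fixation genes fell. Of 16 carbon fixation genes FBA2, an aldolase, fell by 0.43 (SE 0.10, adjusted p = 0.0479; 6 adjusted over the list alone; camera adjusted p = 0.363). The FBA2 call ended without wild-type HD replicate 2 (-0.36), wild-type standard replicate 1 (-0.34), dcl1 HD replicate 1 (-0.40) or dcl1 standard replicate 2 (-0.41), and with DESeq2 size factors, at a mean of at least 10 CPM, on thinned counts and without repeat loci (-0.43 in each). Without wild-type standard replicate 2 or dcl1 HD replicate 2, 2 genes of this list fell. Without wild-type HD replicate 1 both lists passed camera (adjusted p = 0.0111 each), as they did without wild-type standard replicate 2 (0.0284 and 0.0153), and carbon fixation also passed without dcl1 HD replicate 2 (0.0499). Of 19 cold and abscisic acid genes COR47 fell by 0.52 (SE 0.11, adjusted p = 0.0238; 1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.437), and its call ended without dcl1 HD replicate 1 (-0.53) or 2 (-0.50) or dcl1 standard replicate 2 (-0.40). In the other 12 lists that could be tested 0 members passed by edgeR, also adjusted over the list alone (13 of 241 at an unadjusted p under 0.05, and 0 by DESeq2), and their camera adjusted p ran from 0.389 to 0.974. They include the 81 microRNA targets (adjusted p = 0.781), the 17 salicylate genes (0.837) and the 13 senescence genes (0.974). Camera, the median and the mean differed in sign for the lists of microRNA targets, flavonoid, salicylate, clock, senescence and reference genes. AT1G67865 (-0.65, SE 0.10) and TRX3, a cytosolic thioredoxin (-0.54, SE 0.10), were also lower with HD adapters.

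Within wild type 49 loci differed between adapters, 45 higher and 4 lower with HD adapters, and within dcl1 34 were higher and 0 lower by edgeR (1333 at an unadjusted p under 0.05 and 73 by DESeq2). With a block for the RNA sample the counts were 185 (117 higher and 68 lower) and 275 (174 higher and 101 lower), so the calls were less one-sided. Without repeat loci they were 20 and 3, of 27 and 9 called loci without a run, and without a filter 84 and 88. The count within dcl1 was 20 without dcl1 HD replicate 2, 67 without dcl1 HD replicate 1, 53 without wild-type standard replicate 1 and 55 without dcl1 standard replicate 2. The adapter fold change correlated weakly across 19442 genes with GC content (Spearman rho -0.0571) and with transcript length (rho -0.0934), and across the 8968 genes with a mean of at least 10 CPM rho was -0.0964 and -0.108. Per genotype these were -0.0318 and -0.0771 in wild type and -0.0586 and -0.0558 in dcl1.

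The spread between replicates was compared between adapters. The common BCV of thinned counts was 0.344 over 4 HD libraries and 0.303 over 4 standard libraries, as values without a test. At 8 to 32 CPM, the range of DCL1, the SD over 6388 loci of the log2 difference between replicates was 0.463 in wild-type HD, 0.390 in wild-type standard, 0.481 in dcl1 HD and 0.495 in dcl1 standard libraries. The difference between the replicates of an HD pair correlated across loci with that of the standard pair of the same genotype by a Pearson r of 0.182 in wild type and 0.0651 in dcl1 at 8 to 32 CPM. Above 512 CPM, where UBQ10 and LOX2 lie, r was 0.769 and 0.661.

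**Figure D4:**
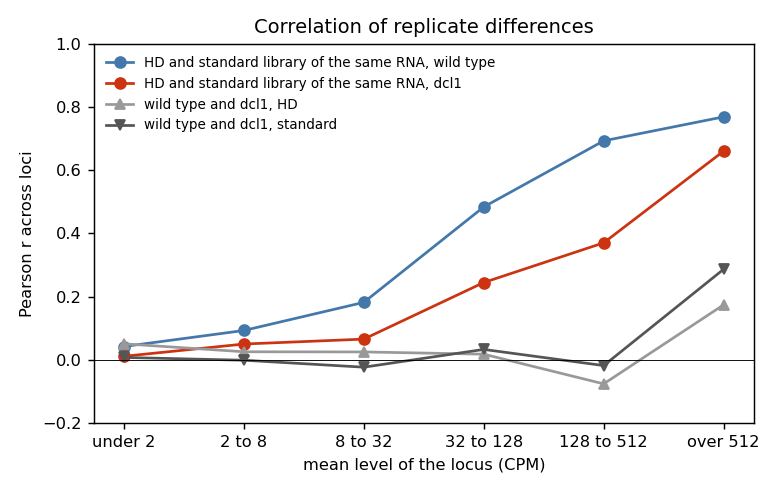
Pearson r across loci of the log2 difference between replicates 1 and 2 in one pair of libraries with that in another pair (y axis), by mean level of the locus (x axis, CPM). Circles compare HD with standard libraries of the same RNA and reach 0.769 in wild type and 0.661 in dcl1 above 512 CPM, and triangles compare wild type with dcl1 and reach 0.286 at most.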

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

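The tests on repeat runs, on removing a trend on GC content and length, on differences between the RNA samples and on few amplified molecules were chosen only after the result was seen.

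AT3G43990, which codes for a protein with a BAH domain, drew attention because its dcl1 effect differed between adapters (interaction -1.98 on the log2 scale, adjusted p = 0.000683 by edgeR). It stood at 1415 ± 129 CPM in wild-type HD libraries (SD, n = 2) and between 355 and 474 CPM in the other 3 groups, and it shares 0% of its 50-base words with another locus. AT1G15405 differed in the same way (-2.80, adjusted p = 0.00289), at 73.9 ± 22.1 CPM in wild-type HD, 14.2 ± 1.37 in wild-type standard, 15.2 ± 6.28 in dcl1 HD and 20 ± 4.14 in dcl1 standard libraries, and shares 100% of its words. AT3G22142 went the other way (2.02, adjusted p = 0.00913), at 29.1 ± 1.70, 63.1 ± 1.54, 19.5 ± 0.551 and 10.5 ± 2.39 CPM in the same order, and shares 90.1% of its words. The 5.8S ribosomal RNA loci AT2G01020 and AT3G41979, with identical counts, differed by -1.247 (adjusted p = 0.0495), at 13292 ± 2147 CPM in wild-type HD libraries and 7205 ± 997, 5475 ± 1061 and 7044 ± 1960 CPM in the others. The groups held too few libraries for a test of single libraries that stand apart.

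For the first pattern weighed, the 83 loci higher with HD adapters, chance was examined with other splits of the libraries. Of 34 splits of the 8 libraries into 4 and 4, only the real one gave as many calls (1 split, with 96 calls against 14 at most in the others). These splits ignore that libraries share RNA samples. With the RNA sample as a block the real split gave 232 calls against 8 at most in the other splits that part every pair. Only 8 splits part every pair, the real one included, too few for a share under 0.05, so chance is not decided by them. Depth is argued against by the thinned counts, which gave 76 loci higher, and a trend on GC content and length as the whole cause of the folds by the median log2 fold change of the 83 loci, 1.41 (SD 1.24) before and 1.41 (SD 1.11) after this trend was removed from each library. Their part in single calls stays open. Spearman correlations reached -0.0934 over all loci and -0.108 at a mean of at least 10 CPM, around the bound set. With the trend removed 49 of the 83 loci kept their call. In the 34 others (median 1.21, SD 1.51, before and 1.07, SD 1.2, after) the fold was smaller in 33 and the SE larger in 29. Of these 34 loci 33 stayed at an unadjusted p under 0.05, but only 9 had a p no higher than the highest called before. It also stays open that reads of simple repeats were counted at every locus that carries the repeat: the odds of a repeat run of at least 40 bases were 325 times those of other loci, and 4 of the 34 loci that lost their call carry one. This may account for 38 of the 83 loci, leaves the other 45 aside, and no biological explanation was tested, since both adapters were used on the same RNA.

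The second pattern is the spread between replicates at 8 to 32 CPM. Differences between the RNA samples as its main source are argued against by the low correlation of the replicate differences of HD and standard libraries of the same RNA, at most 0.182. Counting error is argued against by its share of that variance, 6.51% at most. A candidate explanation that stays open is few amplified molecules behind many reads: the variance beyond counting error fell with abundance with log-log slopes of -0.70, -0.66 and -0.71, between the bounds set for and against it, and of -0.497 in wild-type standard libraries, just past the bound against it. No biological explanation was tested beyond that of differences between the RNA samples.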

How the results depend on the processing

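Leaving out ribosomal RNA, repeat or shared-word loci was chosen only after the result was seen. Of 4489 values of named loci under alternatives 4179 kept direction and side of the threshold, 140 lost the call, 145 gained one, 0 reversed, and 25 changed sign without a call. The number of called members of a list moved by over 1.5 times in 195 of 1101 values, 98 of them among the 480 with a library left out. Where a library was left out the filter kept more loci, so the adjustment ran over more. For the dcl1 effect with HD adapters 20088 to 20576 loci were then tested, against 19521. Without ribosomal RNA loci 19588 were tested there, without repeat loci 19441 and without shared-word loci 18553. The cause of the moves was not tested. Without a filter the dcl1 effect with HD adapters gave 1332 calls, the adapter effect 190 over both genotypes, 84 in wild type and 88 in dcl1, and the interaction 16. At an absolute log2 fold change of at least 1 the dcl1 effect gave 541 calls with HD, 483 with standard adapters and 817 on the sums. DESeq2's test gave 1247 for the dcl1 effect with standard adapters, 179 for the adapter effect and 73 in dcl1. A replicate block gave 232, 185 and 275 for the adapter effect over both genotypes, in wild type and in dcl1, and 36 for the interaction; for the dcl1 effect it gave 1114, 1121 and 2173, within 1.5 times of each count, and changed no list call in any comparison. The share of higher loci in the adapter effect, 86.5%, was 63.8% with the block and 68.7% by DESeq2. Without repeat loci the adapter effect gave 33, 20 and 3 calls, of 58, 27 and 9 called loci without a run. The interaction gave 3 calls with DESeq2 size factors, at a mean of at least 10 CPM and without ribosomal RNA loci, and 1 without shared-word loci. At a mean of at least 10 CPM, r between adapters was 0.752 and rho with GC content -0.0964 and with length -0.108. On counts as deposited the BCV was 0.383 (HD) and 0.340 (standard), and loci with at least 10 counts numbered 18276.8 and 18279. With an estimated correlation, a setting that also has few degrees of freedom, 0, 0 and 0 lists passed in the dcl1 comparisons. Leaving out 1 library gave 461 to 1089 calls for the dcl1 effect with HD and 418 to 996 with standard adapters, 20 to 67 for the adapter effect in dcl1, 3 to 13 for the interaction, and 0 to 2 lists between adapters. Among the 846 calls with HD adapters 1 changed sign without dcl1 HD replicate 2. The contrasts were fitted to counts, but the log2 CPM values behind the replicate differences include a pseudocount, which was not varied. Leaving out organelle loci was not run, since the files list none. Depth limits loci near the floor: 4439 loci averaged under 2 CPM.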

Other observations

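No test in this part was chosen only after its result was seen, but the sulfur genes were looked up because SDI1, LSU1 and APR3 stood among the strongest calls.

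Genes of the O-acetylserine cluster, which plants raise together when sulfur is short, were higher in dcl1 leaves. On the summed counts SDI1 rose by 5.09 on the log2 scale (SE 0.35), to 23.5 ± 8.94 CPM from 0.721 ± 0.318 (SD, n = 2 each), LSU1 by 4.76 (SE 0.32) and APR3, a reductase of sulfate assimilation, by 2.87 (SE 0.17). The hypothesis was that the other members of the cluster move with them, and 3 of the 3 not yet looked at were called higher by edgeR: SDI2 (2.66, SE 0.30), SHM7 (2.26, SE 0.18) and GGCT2;1 (3.32, SE 0.32, adjusted p = 3.73e-06). All 6 were called with each adapter too, except that GGCT2;1 missed the threshold by DESeq2 with standard adapters (adjusted p = 0.0618). These 6 genes rose together, which is consistent with a sulfur-deficiency response in the dcl1 samples, but sulfur was not measured, and 2 samples a genotype cannot tell a genotype effect from growth conditions.

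A segment of another strain carried along with the dcl1 mutation could give calls near DCL1. Of 468 tested loci within 2 Mb of DCL1, 35 were called on the sums (7.48%), against 8.90% of the other loci, an odds ratio of 0.827 (95% interval 0.567 to 1.17, Fisher's exact test, two-sided, p = 0.323). An enrichment of 2-fold or more is outside that interval. The test takes neighbouring loci as independent, so the interval may be too narrow. A segment that changed few loci, or differences elsewhere in the genome, cannot be excluded by it.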
